A study of Mus musculus with 6 samples.

How the data were processed

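ATAC-seq libraries came from limb explants of CD-1 mice, collected 1 day post amputation after culture at an air-liquid interface or in 96-well plates, with 3 libraries per condition. Per the labels' protocols, 4 limbs of each culture were collected, dissociated in trypsin, processed with a Diagenode ATAC-seq kit and sequenced as paired ends on a NovaSeq X Plus. It is not stated whether each library had its own 4 limbs or whether the replicates of a culture came from separate animals. Trim Galore 0.6.10, Bowtie2 2.5.1, SAMtools 1.16.1, Picard, deepTools 3.5.1 and the build GRCm39 are named per the submitters' processing notes, with no role or order. Whether reads were shifted for the Tn5 insertion offset, filtered for duplicates or restricted by fragment length is not given in the sources used here. A missing shift would move profiles by a few bases, within 1 bin.

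The deposited table holds signal, that is depth-normalized coverage, per the file headers, computed by deepTools in bins of 20 bp from 1000 bp upstream to 1000 bp downstream of 235 transcription start sites (TSSs), giving 100 bins for each of the 6 libraries. The track names state normalization to sequencing depth but not its formula. Rows with only zeros were skipped by the authors, per the file headers. How the 235 genes were chosen is not given in the sources used here, and counts of calls describe this set, not the genome. If the genes were chosen on these same libraries, the list tests (fry, camera, Fisher's exact test and the matched lists) are not independent evidence. Bin signal ranged from 0 to 317. No pair of libraries held identical values: at least 99.5% of bins differed between any of them. Gene symbols were used as the table gives them, and 217 matched a RefSeq symbol of GRCm38.p6, which was used for gene class only (186 protein-coding, 31 long non-coding RNA), while 18 did not match. Coordinates come from the table, counted from 1. No annotation of GRCm39 was used, so exons and untranslated regions in the windows are not described. The windows of Asl and Crcp overlap.

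Low bin values within a library were whole multiples of 1 step to within 0.1 of a step (100% of those examined). The step was taken as the signal of 1 base of a read in a bin. Scaled up to a whole bin, it gave the signal of 1 read per base. That signal was 0.139, 0.117 and 0.108 in the 96-well libraries and 0.146, 0.0871 and 0.0977 in the ALI libraries. If the authors' scale factor depends on the number of reads alone, this gives a 1.68-fold range of depth, and a mean coverage of 72.5 to 213.6 reads per base over the windows. Total reads are unknown, the values are coverage and not independent read counts, and no count test was run. Precision is therefore given by the spread between libraries, not by counting error.

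The mean over each window was taken as log2(signal + pseudocount), with the pseudocount at 1.06, which is 0.1 of the median promoter signal. The test was limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend), ALI minus 96-well over all 6 libraries, with Benjamini-Hochberg adjustment over the 235 promoters and a threshold of 0.05. No promoter was at 0 in every library, so none was removed. Library measures were compared by exact two-sided permutation over the 10 splits of 6 libraries into 3 and 3, for which the smallest p is 0.1. Gene lists were tested with limma fry and with camera, with a preset and with an estimated correlation. The medians of 4 lists (ridge signals, developmental genes, immune signalling, and cell division and DNA repair) were also set against 10000 lists each, drawn from promoters of nearest mean signal, after centring and after cyclic loess. Standard errors of changes are those of the moderated limma fit. Its prior degrees of freedom were infinite on the deposited and centred values, so there the trend alone set each variance.

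The groups, the test, the deposited scale for the main result, the alternative settings, 17 gene lists and the rule for named genes were fixed before the data were examined. Alternative settings were other pseudocounts, a filter that dropped the 58 promoters of lowest signal, median centring, quantile normalization, scaling to equal flanks, the central 400 bp only, a replicate block, eBayes without trend and leaving out each library. The rule named the 10 promoters with the largest change in each direction among those past the threshold with non-overlapping groups, or the 5 largest non-overlapping changes where fewer than 5 passed, up to 4 members of each fixed list by p, and Fgf8 by name. Because the deposited scale gave no calls, the same rule was applied to the median-centred fit as well, a choice made after seeing the data.

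Also chosen after seeing the data were removal of the trend between signal and change by cyclic loess, the combinations of centring with other choices, and 9 further gene lists. The group of 43 developmental genes was drawn from the gene names after library means had been seen and before any value of a single promoter, and its division into Wnt, BMP, Notch, FGF, Dlx and Sp, and matrix and adhesion lists was written after promoter values had been seen. The immune signalling list (15 genes) and the cell division and DNA repair list (8 genes) were chosen after their values were seen. Promoters named outside the rule, such as further developmental genes, were likewise chosen after their values were seen.

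The test was tested on simulated data with the libraries' own offsets, 235 promoters, 40 of them changed, a residual SD of 0.18 and 20 draws. Without scaling it recovered 0.5% of log2 changes of 0.3 and 9.75% of those of 0.6. After median centring it recovered 21.2% and 86.2%, with 2.22% of calls false, and after cyclic loess 19.5% and 84.5%, with 2.98% false. The simulation held 1 offset per library and independent noise of equal SD. It held no trend of change with signal, no mean-variance trend and no correlation between promoters. Its recovery and false shares therefore need not hold for the real libraries. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.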

Results

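Chromatin accessibility was measured by ATAC-seq, in which the Tn5 transposase inserts sequencing adapters into open DNA, in amputated limb explants of wild-type CD-1 mice, an outbred stock. All explants were taken 1 day after amputation. Explants cultured at an air-liquid interface (ALI) gave 3 libraries, and explants cultured in 96-well plates gave the other 3. The title of the series names oxygen sensing at the start of limb regeneration as its subject, and the comparison asks how promoter accessibility differed between the culture conditions. The labels do not say whether the libraries of a group came from separate animals, so p-values measure the spread between these libraries, which may be technical. On the deposited and centred values, limma took the variance of each promoter wholly from the mean-variance trend. Its p-values and standard errors there reflect spread shared by promoters of similar signal, not the spread of the single promoter. The deposited table covers a chosen set of promoters, each measured from 1000 bp upstream to 1000 bp downstream of the transcription start site (TSS), in GRCm39 coordinates per the submitters' processing notes. All 13 apical ectodermal ridge genes of a list fixed before the data were examined were in that set, together with 1 hypoxia target (Mxi1), 1 limb mesenchyme gene (Msx1) and 1 matrix gene (Fn1). Relative sequencing depth, read from the signal that 1 read adds, ranged from 0.77 to 1.29 of the mean over the 6 libraries.

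Promoter accessibility formed 1 peak centred 30 bp upstream of the TSS in both cultures, and the peak stood higher over its surroundings in the ALI libraries. Mean signal in the bin at −30 bp was 40.3 ± 11.9 (SD, n = 3) in ALI and 30.8 ± 7.39 (SD, n = 3) in 96-well culture. At the window edges, the outer 200 bp on each side, the means were 5.53 ± 1.06 and 5.12 ± 0.92. The ratio of the central 400 bp to those flanks was 5.69 ± 0.55 in ALI and 4.79 ± 0.27 in 96-well explants. The lowest ALI library had a ratio of 5.17 and the highest 96-well library 5.09. This separation gave an exact two-sided permutation p = 0.1, the smallest p that 3 libraries against 3 allow, and a Benjamini-Hochberg adjusted permutation p of 0.5 over 8 library measures. The groups overlapped with narrower regions (the central 200 bp over the outer 100 bp on each side, difference 1.08, exact permutation p = 0.2) and with the median over promoters in place of the mean (difference 1.61, exact permutation p = 0.2). Mean signal over whole windows was 14.3 ± 3.77 (SD, n = 3) in ALI and 11.7 ± 2.60 (SD, n = 3) in 96-well libraries (exact permutation p = 0.5). That difference of 2.58 was 0.413 without ALI replicate 2.

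**Figure D1:**
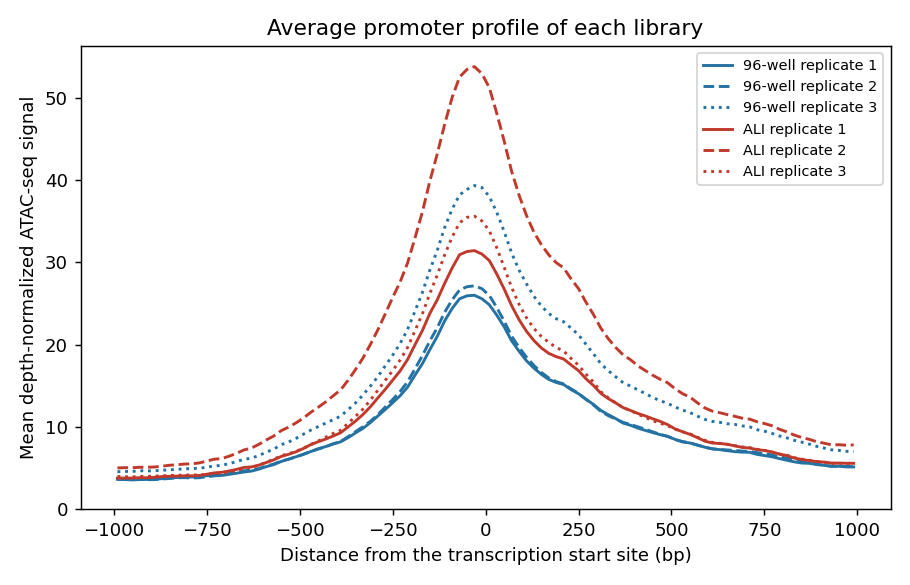
Mean depth-normalized ATAC-seq signal over all promoters of the table (vertical axis) against distance from the TSS in bp (horizontal axis), with 1 line per library, red for ALI and blue for 96-well culture. Every library peaks near −30 bp, and ALI replicate 2 is the highest library with a peak of 53.8.

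After the libraries were centred to a common level, the promoters of Ect2, Khdc4 and Lsm10 were more accessible in ALI explants, and those of Fgf8, Tcf7, Rspo2 and Bcl10 were less accessible. These 7 promoters had non-overlapping groups on that scale, with changes between −0.54 and 0.48 in log2 units. The Bcl10 window was weak, at 1.87 ± 0.09 (SD, n = 3) in ALI and 2.76 ± 0.48 in 96-well libraries. That is near the pseudocount of 1.06 and below the mean signal of all promoters at the window edges (5.53 and 5.12). On the deposited values, the scale fixed in advance for the main test, none of these promoters passed, and limma called 0 promoters (lowest Benjamini-Hochberg adjusted p = 0.40). There, 7 promoters had an unadjusted limma p under 0.05, and 14 promoters (5.96%, against 10% by chance) had non-overlapping groups. Whole libraries differed in level: the median log2 fold change was 0.14 on the deposited values and −0.03 after median centring. Median centring subtracted from each library its median log2 deviation from the promoter means over the 6 libraries. After this centring, listed in advance as a second scaling, limma called 51 promoters (21.7%), 27 higher and 24 lower in ALI, and 92 (39.1%) had non-overlapping groups. Quantile normalization, also listed in advance, called 38 promoters, 19 in each direction. Scaling to equal flank signal called 73, of which 58 were higher and 15 lower in ALI. The 51 calls depended on the mean-variance trend of the limma fit, since 0 were called after centring without it (lowest adjusted p = 0.061). They also fell to 22 without 96-well replicate 1 and to 25 without 96-well replicate 2. Changes below are on the log2 scale of signal plus the pseudocount, ALI minus 96-well after centring, and each was short of the threshold on the deposited values.

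Of the promoters higher in ALI, Ect2, a gene needed for cytokinesis, had the lowest adjusted p. Its signal (chromosome 3, TSS 27208028) was 24.2 ± 4.84 (SD, n = 3) in ALI and 15.1 ± 2.82 in 96-well libraries, a centred change of 0.47 ± 0.09 (SE; limma, Benjamini-Hochberg adjusted p = 0.00011). The promoter of Khdc4, which encodes an RNA-binding protein, changed by 0.48 ± 0.10 (limma adjusted p = 0.00015; chromosome 3, TSS 88593111). Lsm10, which encodes a component of the particle that processes histone mRNAs, changed by 0.38 ± 0.09 (limma adjusted p = 0.0016; chromosome 4, TSS 125990417). The non-coding RNA genes Gm11457 and 9530020I12Rik changed by 0.45 and 0.42. Armc3 and Armc5, both encoding armadillo-repeat proteins, changed by 0.37 and 0.36, and the zinc finger genes Zfp711 and Zfp369 by 0.36 and 0.34. Ppp2r3d, which encodes a regulatory subunit of protein phosphatase 2A, had a signal of 99.5 ± 34.8 in ALI and 61.2 ± 11.98 in 96-well libraries, with a centred change of 0.49 ± 0.14 (limma adjusted p = 0.0058). It was the strongest promoter of every library, so quantile normalization fixed its change at 0 by construction and could not test it. Quantile normalization ended the calls of Armc5 (0.16, limma adjusted p = 0.13) and Zfp369 (0.30, limma adjusted p = 0.070). Removal of the trend with signal by cyclic loess, chosen after seeing the data, left smaller changes at Ppp2r3d (0.13), Armc5 (0.19) and Khdc4 (0.29), all still called.

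Of the promoters lower in ALI, several belong to signalling genes of the limb bud and its ridge. The promoter of Fgf8, the growth factor that marks the apical ectodermal ridge, had a signal of 6.50 ± 1.29 (SD, n = 3) in ALI and 7.84 ± 1.62 in 96-well libraries. Its centred change was −0.40 ± 0.10 (SE; limma, Benjamini-Hochberg adjusted p = 0.0020; chromosome 19, TSS 45731355), and quantile normalization ended the call (−0.25, limma adjusted p = 0.084). Tcf7, a nuclear effector of Wnt signalling, changed by −0.37 ± 0.10 (limma adjusted p = 0.0021; chromosome 11, TSS 52174159), and Rspo2, a secreted enhancer of Wnt signalling, by −0.36 ± 0.09 (limma adjusted p = 0.0023; chromosome 15, TSS 43034223). Bmp4 changed by −0.36 ± 0.10 (limma adjusted p = 0.0045; chromosome 14, TSS 46628127), a call that ended after quantile normalization (−0.23, limma adjusted p = 0.063) and after removal of the trend with signal (−0.22, limma adjusted p = 0.056). Genes with roles in NF-κB or immune signalling were called in both directions, Nfkb2 (0.24) and Psme2 (0.30) higher in ALI and 4 lower, with Cd55 at −0.34, Bcl10 at −0.54 ± 0.18 (limma adjusted p = 0.015), Tifa at −0.43 ± 0.10 (limma adjusted p = 0.00051) and Unc13d, needed for the release of cytotoxic granules, at −0.46 ± 0.11 (limma adjusted p = 0.0011). These genes were grouped after their values were seen, and quantile normalization ended the calls of Unc13d (limma adjusted p = 0.059), Nfkb2 (limma adjusted p = 0.25) and Psme2 (limma adjusted p = 0.14). In the central 400 bp on the deposited scale, Bcl10 and Unc13d had changes of the opposite sign (0.02 and 0.11), short of the threshold. The changes of Tcf7 and Rspo2 there were −0.035 and −0.069. With that central region, Tcf7 was not called after centring, and neither Tcf7 nor Rspo2 after removal of the trend with signal, whereas Fgf8 was called under both. The remaining named promoters were the non-coding RNA genes Gm10804 (−0.55) and Gm9918 (−0.50) and Dnajc6 (−0.41), which encodes a clathrin-uncoating factor. After removal of the trend with signal, the changes of Fgf8 (−0.25), Unc13d (−0.29) and Gm9918 (−0.32) were smaller but still called, and the call of Dnajc6 ended (−0.23, limma adjusted p = 0.056). On the deposited values the largest non-overlapping decreases also took in 9630028H03Rik (−0.29) and Slc4a10 (−0.20), which were called neither there nor after centring.

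Of the other fixed lists, 13 had no member in the table, glycolysis, oxygen sensing and cell type markers among them. The hypoxia list was represented by Mxi1 alone, a Myc antagonist, whose promoter was lower in ALI after centring (−0.28 ± 0.09, limma adjusted p = 0.013) and after quantile normalization, with a deposited change of −0.11. Without 96-well replicate 3 the deposited change of Mxi1 was 0.06. The limb mesenchyme gene Msx1 had a centred change of −0.19 (limma adjusted p = 0.12). The matrix gene Fn1, which encodes fibronectin, had a centred change of 0.27 (limma adjusted p = 0.051) and was called higher after scaling to equal flank signal, but its change was 0.06 (limma adjusted p = 0.14) after quantile normalization and 0.04 (limma adjusted p = 0.55) after removal of the trend with signal.

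**Figure D2:**
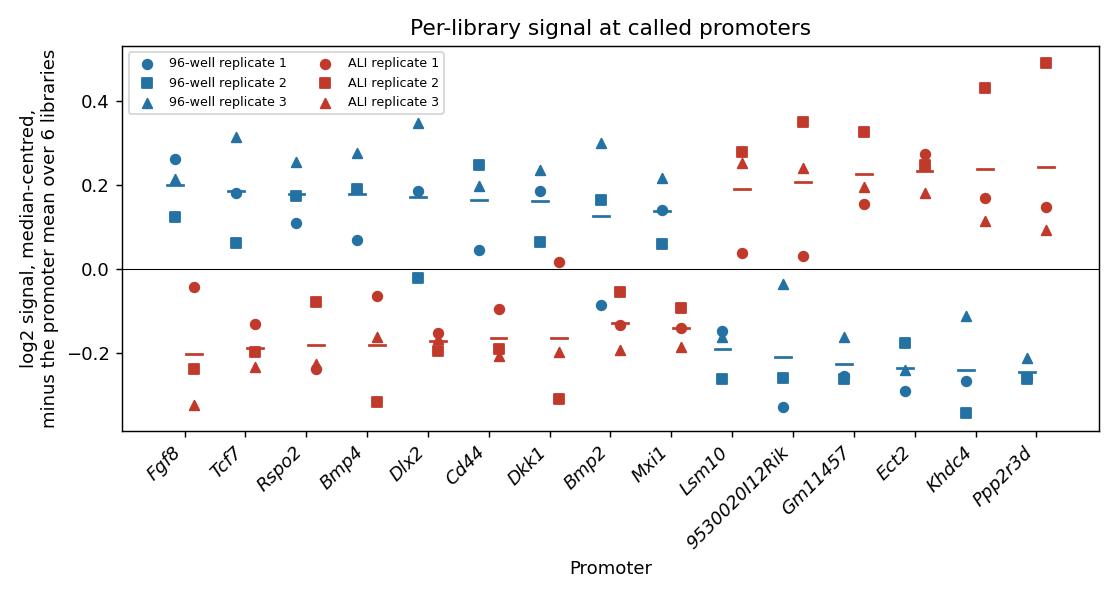
Log2 signal per library after median centring, minus the mean of that promoter over the 6 libraries (vertical axis), for the 8 developmental promoters called lower in ALI, for Mxi1 and for the 6 called promoters with the largest non-overlapping increase. Symbols are single libraries, red for ALI and blue for 96-well, and short bars are group means, such as those of Fgf8, which differ by −0.40. None of these promoters was called on the deposited values.

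After median centring, 12 of the 13 promoters of apical ectodermal ridge signals had a negative change, with a median of −0.19 against −0.02 for other promoters of the table, and 2 were called lower (Fgf8 and Bmp4) and 0 higher, with the same 2 lower and 0 higher adjusted over the list alone. The epithelial regulator Trp63 (−0.40, limma adjusted p = 0.14) and Fgf17 (−0.32, limma adjusted p = 0.10) stood lower without passing. Relative to other promoters within each library, the 13 lay at −0.55 ± 0.07 (SD, n = 3) log2 units in ALI and −0.36 ± 0.02 in 96-well libraries (exact permutation p = 0.1, the smallest possible). The centred median was at percentile 5.24 of 10000 lists matched on signal, within their middle 95% range (−0.23 to 0.06), and after removal of the trend with signal at percentile 3.77, again within that range. By the rotation test fry of limma, the set missed the threshold over 10 lists (Benjamini-Hochberg adjusted p = 0.061) after centring, and passed it after quantile normalization (adjusted p = 0.0080) and after removal of the trend with signal (adjusted p = 0.048). Against other promoters, camera of limma after centring gave adjusted p = 0.0083 with a preset correlation and adjusted p = 0.42 with an estimated one. After quantile normalization camera did not pass with either (adjusted p = 0.15 and 0.30), nor after removal of the trend with signal (adjusted p = 0.14 and 0.32). On the deposited values the set median was −0.03, with 0 of 13 called in either direction (limma), 0 adjusted over the list alone and an adjusted fry p of 0.94. That median changed sign without 96-well replicate 3 (0.11), ALI replicate 1 (0.01) or ALI replicate 3 (0.04).

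A wider group of 43 developmental promoters, formed from gene names after the table was opened and holding the 13 ridge genes, had called decreases after centring, and whether it also had called increases depended on the setting. With all 6 libraries and whole windows, 8 were called lower in ALI by limma, namely Fgf8, Tcf7, Rspo2, Bmp4, Bmp2, Dlx2, Cd44 and the Wnt inhibitor Dkk1, against 0 higher, whereas the other promoters of the table gave 16 lower and 27 higher. The share called higher was 0% against 14.1% of other promoters (Fisher's exact p = 0.0061, Benjamini-Hochberg adjusted p = 0.0082 over 4 such tests), and the share called lower was 18.6% against 8.33% (Fisher's exact adjusted p = 0.054). These tests treat promoters as independent, which promoters of the same libraries are not. Relative to other promoters within each library, the group lay 0.24 ± 0.07 (SD, n = 3) log2 units higher in 96-well and 0.10 ± 0.04 higher in ALI libraries (exact permutation p = 0.1, the smallest possible). After centring, camera of limma gave adjusted p = 0.0011 with a preset correlation and adjusted p = 0.42 with an estimated one. The median change was −0.15 after centring, −0.12 after quantile normalization and −0.08 with equal flanks, but 0.02 on the deposited values, where 0 were called. Quantile normalization called 6 lower and 0 higher, and of the 8 above only Tcf7 and Rspo2 were among them. The absence of increases did not hold throughout. Fn1 and Axin2 were called higher with equal flanks (6 others lower), and after centring without the 58 weakest promoters (20 lower), without 96-well replicate 3 (5 lower) or without ALI replicate 2 (7 lower). After centring, Fn1 was also called higher without ALI replicate 3 or with the smaller pseudocount, and Axin2 in the central 400 bp.

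Within this group, Wnt pathway promoters had 3 of 10 called lower after centring (Tcf7, Rspo2 and Dkk1), while Axin2, a Wnt target, stood at 0.24 and Wnt5a at −0.17 without passing. BMP pathway promoters had 2 of 6 called lower (Bmp2 and Bmp4), FGF ligands 1 of 4 (Fgf8), Dlx and Sp transcription factors 1 of 7 (Dlx2) and matrix and adhesion genes 1 of 7 (Cd44). None of the 6 Notch pathway promoters was called by limma, Jag2 at −0.23 included. Adjusted over all promoters, no member of these 6 lists was called higher after centring at the main settings. Adjusted over the list alone, the Wnt list had 1 higher and 4 lower, and the matrix and adhesion list 1 higher and 2 lower. Their fry tests on the centred values gave adjusted p between 0.061 and 0.30, so none passed, and with an estimated correlation camera gave adjusted p between 0.42 and 0.74. After quantile normalization, fry of limma passed for the Wnt (adjusted p = 0.013), BMP (adjusted p = 0.024), Notch (adjusted p = 0.0076) and FGF lists (adjusted p = 0.021), all downward in ALI. After removal of the trend with signal it passed for the Wnt (adjusted p = 0.024), BMP (adjusted p = 0.048) and Notch lists (adjusted p = 0.024). With an estimated correlation, camera called none of the lists under either scaling (lowest adjusted p = 0.30 and 0.32). The division into these lists was written after promoter values had been seen, and several members also belong to the ridge list. The fry passes are therefore not independent support for separate pathways.

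**Figure D3:**
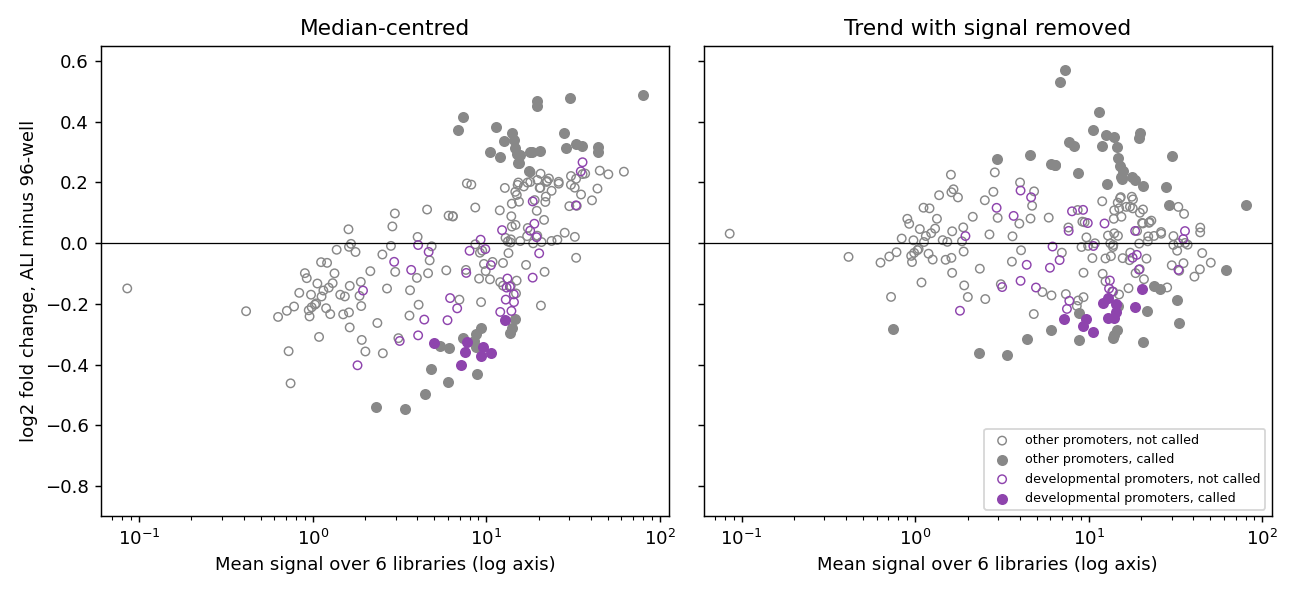
Log2 fold change, ALI minus 96-well (vertical axis), against mean signal over the 6 libraries (horizontal log axis), after median centring (left) and after removal of the trend with signal (right). Each point is a promoter, purple for the 43 developmental promoters and grey for others, and filled where limma called it. The 27 filled points above 0 on the left are all grey, and the 24 below 0 include 8 purple ones. On the deposited values no point would be filled.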

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

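Cyclic loess, centring combined with other choices and scalings of the gene list other than centring were chosen after the results were seen. On the deposited values 0 promoters were called under the other pseudocounts, the low-signal filter, the central 400 bp, eBayes without trend and each library left out (range 0 to 0), whereas median centring gave 51, quantile normalization 38, equal flanks 73 and cyclic loess 61 (31 higher, 30 lower). The scalings differ from the deposited scale by a library offset or more, and simulated changes of 0.6 were recovered at 9.75% without scaling and 86.2% with centring. For simulated changes of 0.3 the shares were 0.5% and 21.25%. Centred changes in the data ranged from −0.55 to 0.49, so none reached 0.6, and the simulation held no trend with signal. After centring, the count was 29 with the pseudocount equal to the median signal, 90 without the 58 weakest promoters and 0 with eBayes without trend. The cause was not tested. Leaving out 1 library gave 22 to 58 calls, with 22 without 96-well replicate 1 and 25 without 96-well replicate 2. After cyclic loess the range was 34 to 69, with 34 without 96-well replicate 3, and 39 were called without the variance trend. Of the 51 centred calls, 36 were shared with cyclic loess and 25 with quantile normalization. The 23 called under all 3 scalings were 14 higher, Ect2 and Timeless among them, and 9 lower, Tcf7, Rspo2, Bcl10, Tifa, Cd55 and Mxi1 among them. These were whole-window calls: in the central 400 bp, Tcf7 was not called after centring, and neither Tcf7 nor Rspo2 after cyclic loess. Without 96-well replicate 3, the deposited changes of Tcf7 and Rspo2 were −0.005 and −0.019.

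The ridge list median of −0.03, short of the unadjusted 0.05 threshold of fry, became −0.194 with centring, −0.116 with quantile normalization, −0.127 with equal flanks, −0.0713 with cyclic loess and −0.285 with centring in the central 400 bp, each past it. Leaving out 1 library gave −0.18 to 0.11 on the deposited values, with the sign reversed without 96-well replicate 3 (0.11), ALI replicate 1 (0.01) and ALI replicate 3 (0.04). After centring it gave −0.24 to −0.18, passing without ALI replicate 1, 2 or 3 (−0.24, −0.18 and −0.18) and falling short without any 1 of the 96-well libraries. Single promoters that reversed on the deposited values were Bcl10 (0.0206) and Unc13d (0.11) in the central 400 bp, Mxi1 without 96-well replicate 3 (0.0635, range −0.283 to 0.0635 with 1 library left out), and Msx1 without 96-well replicate 3 (0.21), ALI replicate 1 (0.12) or ALI replicate 3 (0.01; range −0.186 to 0.205). The cause was not tested. The difference in mean signal stayed positive (0.413 to 4.08 with 1 library left out), as did that in the centre to flank ratio (0.614 to 1.164), and no exact p went below 0.1, the least the design allows.

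With the replicate number as a block, 0 promoters were called on the deposited values and 39 after centring, all 39 among the 51, and the centred ridge list (median −0.194) no longer passed fry. The numbers showed no consistent pairing: the correlation of same-numbered deviations was 0.67, −0.61 and −0.60, and only 96-well replicate 1 correlated best with its own number. These centred deviations still held the trend with signal, which could mask a shared origin, so pairing is not excluded. Read depth is known only relatively, so it sets no limit for single promoters.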

Other observations

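The calls on the deposited values and after centring were planned, whereas the cyclic loess, the cell division and immune lists, the tests of explanations and the counts over splits were chosen only after the results were seen, and the developmental group was drawn from gene names once library means were known. Of 8 promoters of cell division and DNA repair genes, 4 were called higher after centring by limma and 0 lower, namely Ect2 (0.47), the histone mRNA binding gene Slbp (0.32), the end-joining gene Nhej1 (0.31) and the replication fork gene Timeless (0.29), while Rbl1 (0.11), Slx4 (0.20), Dclre1b (0.01) and Rint1 (−0.03) were not called. After cyclic loess removed the trend with signal, 3 stayed called, and the list median was at percentile 76.02 of lists matched on signal (96.91 after centring). Of 15 immune signalling promoters, Bcl10, Tifa, Unc13d and Cd55 were called lower and Nfkb2 and Psme2 higher after centring, and after cyclic loess 4 were lower and 0 higher, with the list median at percentile 55.6 (17.64 after centring). Both lists were chosen after the values of their members were seen, so these values do not decide whether either group moved as 1. Long non-coding RNA promoters were weak, with a median signal of 1.86 in ALI and 2.20 in 96-well libraries, and 3 of 31 were called higher and 3 lower after centring.

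Change followed promoter strength. Across promoters, which are not independent replicates, the rank correlation of change with mean signal was 0.66, and after centring 12 of the 59 strongest promoters were called higher and 0 lower, against 3 higher and 18 lower among the 59 next above the 59 weakest. Steeper enrichment of strong promoters in the ALI libraries, which had the higher centre to flank ratios, may account for part of this. Libraries of a culture did not move together at every promoter. At Cyp2b13 and Litafd, for example, centred values minus the promoter mean were −0.52 and −0.46 in ALI replicate 2. They were −0.34 and −0.49 in 96-well replicate 3, but 0.09 and 0.14 in ALI replicate 1 and 0.10 and 0.05 in ALI replicate 3. ALI replicate 2 and 96-well replicate 3 had the highest levels (log2 offsets 0.38 and 0.20). Whether the trend partly followed library level was not tested. Over all 51 centred calls, cyclic loess took the median change in the called direction from 0.33 to 0.25. It kept the direction of all 51 and left 36 called, although some of these shrank strongly (Ppp2r3d from 0.49 to 0.13). A trend with mean window signal, as loess fits it, was therefore not the whole source of the 36. Loess does not adjust for the centre to flank ratio, so steeper enrichment stays open for them. No other split of the libraries gave a call after loess, but each of those mixed the cultures, so that decides nothing. The other 15, Bmp4, Cd44, Dkk1 and Slbp among them, went from a median absolute change of 0.32 to 0.17, a ratio of 0.519. The median of their single-promoter standard errors went from 0.10 to 0.08. Promoters picked for losing their call will show smaller changes, so this decides nothing, and for them enrichment and culture cannot be told apart, since the 3 libraries with the lowest centre to flank ratio are the 96-well libraries. The 3 deepest libraries against the 3 shallowest gave 1 call after centring, provided the signal of 1 read per base tracks depth. Each side of that split held both cultures, so a culture difference would widen the spread within sides. Few calls were likely either way, and an effect of depth stays open.

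The 10 splits of 6 libraries are too few for a share under 0.05. The real split gave 0 calls on the deposited values, as few as any, with all 10 splits giving as many and the highest of the others at 2. It gave 51 after centring (highest other 1) and 61 after cyclic loess (highest other 0), and in both 1 of the 10 splits, the real one, gave as many. Every other split mixed the cultures on both sides, which would widen the spread within sides. Few calls were likely there either way, so these counts decide nothing.

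The lower accessibility of developmental promoters relative to other promoters is a hypothesis that outlasted trend removal. On the deposited values their median change was 0.02, against 0.17 for other promoters, and 0 of the 43 were called. After cyclic loess, 12 of the 43 were called lower (Fgf8, Tcf7, Rspo2, Lef1, Jag2, Wnt5a, Bmp2, Bmp7, Dlx2, Dlx6, Msx1 and Col4a1) and 0 higher, against 18 lower and 31 higher among other promoters (Fisher's exact adjusted p = 0.0076 in each direction). The Fisher tests treat promoters as independent, which they are not. The list median of −0.0879 lay below the middle 95% range of 10000 lists matched on signal (−0.01 to 0.08). This argues against a trend with mean window signal as the whole source. The match did not cover the centre to flank ratio, so steeper enrichment in the ALI libraries is not excluded. With an estimated correlation, camera of limma gave adjusted p = 0.32 over 10 lists, and 3 of the 43 were called lower without 96-well replicate 3. Fewer epithelial cells in ALI explants is a candidate explanation that stays open. The epithelial promoters Cdh1 (−0.08), St14 (−0.16) and Trp63 (−0.22) had a median of −0.161 after cyclic loess, none of them called. After centring, St14 was called lower (−0.34, limma adjusted p = 0.015), while Cdh1 (−0.25, limma adjusted p = 0.080) and Trp63 (−0.40, limma adjusted p = 0.14) were not. Cdh1 and Trp63 belong to the list themselves, and no keratin promoter was analysed here. A response of the ridge and mesenchyme to the culture condition also stays open and was not tested apart from fewer epithelial cells.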
